A study of Mus musculus with 18 samples.

How the data were processed

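Gene expression was measured by RNA sequencing of frozen mouse testis. Per the labels' protocols, RNA was extracted with Trizol and a column kit, and libraries were made from 1 ug of total RNA with a standard Illumina protocol. Per the submitters' processing notes, reads were mapped with Bowtie 0.12.2 to the mm10 mouse genome. The counting tool, the gene annotation and the strand setting are not given in the sources used here. The authors deposited 1 table of 20985 rows with 1 value per gene and library, whose header names no unit. It was read as FPKM, deposited to 2 decimals, because the sums differ between libraries, lie under those of CPM or TPM, and the smallest steps scale with transcript length. Columns were matched to samples by the group letters and replicate numbers in their names.

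The 18 libraries were grouped by the labels into 6 groups of 3. The 6 rows of 3 repeated symbols were left out, as they cannot be told apart. Of the symbols, 26 have the form of dates and name no gene here, and 403 rows were at 0 in every library. Of 20979 symbols, 20219 were matched to the GENCODE annotation of GRCm38, the same assembly as mm10, which gave coordinates, and 98.1% of the genes tested had a transcript length. Relative depth was estimated from 167 genes whose lowest values cluster, with the cluster read as the value of 1 read. Of 1432 values of these genes up to 4.5 such steps, 82.4% lay within 0.15 of a whole step, where an even spread gives 30%. The step of a gene was set from its own lowest values. These are among the 1432 and lie near 1 step by construction, so the 30% is no fair yardstick. The floor on step size for these genes was chosen after looking at the values. Absolute depth is unknown, so no counting interval is given.

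The design, the tests, the gene lists, the naming rule and most alternatives were fixed before the data were examined, with the test to follow from the unit of the values. Values were taken as log2(FPKM + 1), genes with a mean of at least 1 FPKM over the 18 libraries were kept, and 13105 genes were tested. One limma model with 6 group means and a mean-variance trend (limma 3.58.1 in R 4.3.3, 12 residual degrees of freedom) gave log2 fold changes, SE and two-sided p-values, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The 6 comparisons between groups, the difference of the AOS effects with and without the diet, and an F test over all groups came from this model. On simulated data with 100 genes changed by 1 on the log2 scale among 13105, the model recovered 95, 99, 97, 96, 95 and 98 of them in the 6 comparisons, in the order reported, and 90 for the difference of effects. At a change of 0.5 it recovered 80, 84, 79, 83, 85 and 76, and 65 for the difference of effects. Between 5 and 11 unchanged genes were called as well, and 0 changed genes in the wrong direction. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

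Of 31 gene lists written from general knowledge, 29 had at least 5 tested members and were tested with limma's camera at a preset correlation of 0.01, with adjustment over the lists of a comparison. They covered spermatogonia, meiotic spermatocytes, round and elongating spermatids, Sertoli, Leydig and peritubular smooth muscle cells, macrophages and leukocytes, endothelium, blood and adipocytes. The others covered cholesterol biosynthesis, fatty acid synthesis and oxidation, glycolysis, nuclear oxidative phosphorylation, antioxidant defence, inflammation, interferon response, apoptosis, endoplasmic reticulum stress, heat shock, immediate early response, the blood-testis barrier, extracellular matrix, retinoid metabolism, cell cycle, histones and ribosomal proteins. Lists of epididymal and mitochondrially encoded genes had too few members. In a simulation that shifted 1 list of random genes by 0.2 on the log2 scale, camera called that list in each of the 6 comparisons and 0 others. Genes were drawn independently there, so it cannot show how often camera falsely calls lists whose members vary together. Within the lists tested here, estimated correlations ran from -0.0175 for inflammation to 0.42 for the interferon response, with 0.168 for ribosomal proteins. With the correlation estimated per list, 0 lists were called in any comparison.

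Genes were named by a rule. In each comparison it took up to 8 rises and 8 falls of largest fold change among genes with an adjusted p under 0.05, no overlap between the 3 and 3 values, a higher group mean of at least 2 FPKM and no predicted or clone name. It added the 3 members of smallest p of each called list and, where fewer than 5 genes passed in a direction, the 5 genes of smallest p in it. A panel of 16 genes (Star, Cyp11a1, Cyp17a1, Hsd3b1, Hsd17b3, Insl3, Lhcgr, Sycp3, Dazl, Ddx4, Piwil1, Tnp1, Prm1, Sox9, Amh and Stra8) was summarised in every comparison. Some genes are not reported here. Other genes named in the text were chosen after their values were seen.

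The alternatives were a pseudocount of 0.1, no filter on low values or a mean of at least 5, quantile normalization, trimmed-mean scaling, robust empirical Bayes, array weights, only the compared groups in the model, a fold threshold of 1 on the log2 scale, the replicate number as a block, camera with an estimated correlation, fry, and leaving out each of the 18 libraries in turn. An adjustment of each library for transcript length and GC share, and leaving out control 3 and HFD-conFMT 2 together, were added after the data were seen. Correlations between comparisons were set against 1000 draws of unchanged groups with the same shared libraries.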

Results

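RNA sequencing of whole testis was compared across 18 ICR mouse samples taken at 10 weeks of age, in 6 groups of 3. The groups were untreated control, AOS (10 mg/kg), high-fat diet (HFD), high-fat diet with AOS at 10 mg/kg (HFD-AOS), and high-fat diet with FMT labelled either AOS 10 mg/kg (HFD-AOSFMT) or control (HFD-conFMT). AOS and FMT are given as labelled, since the sources used here do not spell them out. The labels do not say whether replicates came from separate animals, so p-values measure the spread between these samples, part of which can be technical. Values summed to between 588159.7 and 637077 FPKM per library. Between 12996 and 13221 genes reached 1 FPKM. The steps between low values gave relative depths of 0.926 to 1.05, while the absolute depth is unknown. Libraries of the same group differed by a median absolute log2 value of 0.078 to 0.14 and libraries of different groups by 0.077 to 0.15. Protamine and transition protein transcripts, which pack sperm DNA, made up 6.46 to 9.07% of each library. Ribosomal protein, globin and kallikrein genes have near-identical copies, so the split of their reads is uncertain. All fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and values are means ± SD with n = 3.

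The comparison of HFD with control asked what the diet alone did to the testis. Late germ cell lists were slightly higher on the diet than in control, whose libraries also serve the comparison of AOS with control. The round spermatid list rose, with 26 of 30 members higher and a median log2 fold change of 0.078 (camera adjusted p = 9.47e-06). It had an adjusted p = 0.285 with an estimated correlation and 1.1e-06 to 0.285 over all alternatives. Among its members, Sun5, which joins the sperm head to the tail, was at 148 ± 6.32 against 126 ± 2.47 FPKM, and the acrosomal gene Spaca7 at 171 ± 4.54 against 149 ± 5.97 FPKM. The elongating spermatid list rose with 24 of 28 members higher, though its median of 0.051 became -0.0020 with quantile normalization (camera adjusted p = 0.000894). With an estimated correlation the list had an adjusted p = 0.285, and all alternatives spanned 9.92e-07 to 0.933. The linker histone Hils1 was at 584 ± 17 against 523 ± 37.3 FPKM. Among lists of short transcripts, that of ribosomal proteins rose with 59 of 82 members higher, and its median of 0.041 became 0.0064 with quantile normalization (camera adjusted p = 0.0035). An estimated correlation gave the ribosomal protein list an adjusted p = 0.659, in a range of 2.13e-05 to 0.933 over all alternatives. The nuclear oxidative phosphorylation list rose with 58 of 82 members higher (camera adjusted p = 0.00515). Over all alternatives the oxidative phosphorylation list spanned 3.76e-05 to 0.744, with an adjusted p = 0.659 with an estimated correlation. Median transcript lengths in these 2 lists were 704 and 637 bases, against 1989 for all genes tested. Over 12851 genes the log2 fold change correlated with transcript length at a Spearman rho of -0.193 and with GC share at -0.00794. Rpl35 was at 615 ± 77.6 against 529 ± 26.7 FPKM and the cytochrome oxidase subunit Cox5b at 166 ± 4.67 against 139 ± 10.8 FPKM. The blood list fell, with a median of -0.57 over 5 members (4 of 5 members lower, camera adjusted p = 0.0311), the alpha globin Hba-a1 being at 62.1 ± 22.9 against 99 ± 12.4 FPKM. The blood list had an adjusted p = 0.285 with an estimated correlation, and 0.00455 to 0.463 over all alternatives. The extracellular matrix list fell with 23 of 26 members lower (camera adjusted p = 0.0311), and collagen Col3a1 was at 6.54 ± 1.64 against 8.19 ± 1.5 FPKM. All alternatives put the extracellular matrix list at 0.000359 to 0.659, with an adjusted p = 0.659 with an estimated correlation.

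No single gene was called between HFD and control by limma (0 of 13105 genes, lowest adjusted p = 0.583 for Kcnip2). At an unadjusted p under 0.05 there were 884 genes, where chance gives 655 in this and every other comparison. The 3 and 3 values did not overlap for 12.5% of genes, where chance gives 10%. Adjusted over the list alone, 0 members of the 6 called lists passed. The smallest p-values above control belonged to Kcnip2 (16.5 ± 0.638 against 13.7 ± 0.872 FPKM), a potassium channel interacting protein, the serine protease gene Prss55 (170 ± 8.23 against 151 ± 1.4 FPKM) and Svs5 (3.23 ± 0.37 against 1.85 ± 0.355 FPKM), a seminal vesicle secretory protein. Also among them was Smim23 (227 ± 2.12 against 176 ± 16.3 FPKM). Those below control were Mmd2 (18 ± 0.146 against 22.3 ± 2.31 FPKM), Zer1 (14.7 ± 0.232 against 16.9 ± 0.331 FPKM) and Ubxn2a (3.04 ± 0.177 against 4.01 ± 0.226 FPKM). Next came the kallikrein Klk1b21 (8.27 ± 3.54 against 21.3 ± 5.28 FPKM) and Boll (77.9 ± 4.67 against 88 ± 1.12 FPKM), an RNA-binding protein of meiosis. Crisp1, an epididymal secretory gene, was at 159 FPKM in control 3 against 2.71 and 0.15 in the other control libraries. Of the processing alternatives, calls ended for all 6 lists with quantile normalization, for the blood list with no filter on low values, with a pseudocount of 0.1 and with array weights, for the extracellular matrix list with a mean of at least 5 FPKM required and without both control 3 and HFD-conFMT 2 and for the extracellular matrix, ribosomal protein and oxidative phosphorylation lists with the length and GC adjustment. Leaving out 1 library ended the call of the elongating spermatid list without HFD 1 (adjusted p = 0.125), of the blood list in 13 of 18 fits (adjusted p = 0.056 to 0.463), of the extracellular matrix list in 4 of 18 fits (adjusted p = 0.153 to 0.408), of the ribosomal protein list without control 2 or HFD 1 (adjusted p = 0.153 to 0.335) and of the oxidative phosphorylation list without control 2 or HFD 1 (adjusted p = 0.0621 to 0.335).

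The comparison of AOS with control asked what AOS did without the high-fat diet. Sterol synthesis transcripts were lower after AOS. The cholesterol biosynthesis list fell, with 20 of 23 members lower and a median log2 fold change of -0.18 (camera adjusted p = 1.92e-06). This call was lost with an adjusted p = 0.352 with an estimated correlation, and alternatives spanned 8.19e-08 to 0.352. Adjusted over the list alone, 11 members fell, and 0 passed over all genes. Msmo1, a sterol methyl oxidase, was at 14.1 ± 1.26 against 22.6 ± 2.08 FPKM (log2 fold change -0.64, SE 0.13), Hmgcs1, the HMG-CoA synthase, at 26.2 ± 1.12 against 33.4 ± 2.27 FPKM and Mvd at 2.09 ± 0.0551 against 3.04 ± 0.522 FPKM. The fatty acid synthesis list fell (14 of 20 members lower, camera adjusted p = 0.0372), with 8 members down and 2 up adjusted over the list alone and 0 over all genes. That list had an adjusted p = 0.518 with an estimated correlation, within a range of 0.00424 to 0.518 over all alternatives. Malic enzyme Me1 was at 150 ± 9.61 against 174 ± 3.04 FPKM, the elongase Elovl5 at 24.6 ± 1.32 against 30.5 ± 1.14 FPKM and the desaturase Fads1 at 26.3 ± 1.4 against 37.9 ± 8.96 FPKM. The Leydig cell and steroidogenesis list fell, with 17 of 19 members lower and a median of -0.14 (camera adjusted p = 0.0166), and 3 members fell adjusted over the list alone. It had an adjusted p = 0.518 with an estimated correlation and 0.000221 to 0.518 over all alternatives. Relative to all libraries, the mean of the Leydig list was -0.166, 0.106 and -0.215 in AOS 1, 2 and 3. In the control libraries it was 0.122, 0.0342 and 0.143, so that AOS 2 lay within the control range. Cyp11a1, which makes pregnenolone from cholesterol, was at 91.7 ± 16.1 against 133 ± 15.2 FPKM, Cyp17a1 at 255 ± 30.6 against 348 ± 36.1 FPKM and the prolactin receptor Prlr at 3.76 ± 0.595 against 5 ± 0.282 FPKM.

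Late germ cell lists were higher in AOS than in control. The comparison of HFD with control uses the same control libraries, so calls that both share are not independent. Relative to all libraries, control had the lowest mean of the 6 groups for the elongating (-0.0771) and round spermatid (-0.0627) lists. It was also lowest for the oxidative phosphorylation (-0.102) and ribosomal protein (-0.0994) lists and highest for the extracellular matrix list (0.113). An unusual control group and effects of each treatment cannot be told apart there. Of the elongating spermatid list 21 of 28 members were higher (camera adjusted p = 5.82e-05), and 1 member rose adjusted over the list alone. With an estimated correlation the list had an adjusted p = 0.352, and all alternatives spanned 6.06e-06 to 0.82. With quantile normalization its median went from 0.065 to 2.7e-15, that of the round spermatid list from 0.0535 to 0.013, and neither was called. The log2 fold change was 0.33 for transition protein Tnp2 and 0.40 for Prm3. The round spermatid list rose (20 of 30 members higher, camera adjusted p = 0.00499), with the testis kinases Tssk2 at 392 ± 17 against 355 ± 7.78 FPKM and Tssk3 at 203 ± 4.73 against 183 ± 3.99 FPKM. An estimated correlation gave the round spermatid list an adjusted p = 0.459, in a range of 0.000714 to 0.56 over all alternatives. The oxidative phosphorylation list rose (62 of 82 members higher, camera adjusted p = 2.15e-08), with 6 members up adjusted over the list alone and Ndufv3, of complex I, at 43.7 ± 2.15 against 33 ± 0.965 FPKM. Over all alternatives the oxidative phosphorylation list spanned 1.7e-09 to 0.459, with an adjusted p = 0.459 with an estimated correlation. The ribosomal protein list rose (60 of 82 members higher, camera adjusted p = 2.15e-07), with 3 members up adjusted over the list alone and Rpl13 at 448 ± 5.61 against 393 ± 6.1 FPKM. The ribosomal protein list had an adjusted p = 0.459 with an estimated correlation, and 1.74e-08 to 0.459 over all alternatives. Beside the rises of the ribosomal protein and oxidative phosphorylation lists, whose transcripts are short, the log2 fold change of 12851 genes correlated with length at a Spearman rho of -0.256 and with GC share at 0.269, and both lists stayed called with the length and GC adjustment. The extracellular matrix list fell with 25 of 26 members lower (camera adjusted p = 0.000292). All alternatives put the extracellular matrix list at 3.85e-05 to 0.459, with an adjusted p = 0.459 with an estimated correlation. The metalloproteinase inhibitor Timp2 was at 53.3 ± 4.36 against 61.6 ± 1.81 FPKM.

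Over all genes limma called 3 between AOS and control. Higd2a, on chromosome 13 from 54590207 to 54591158 (mm10), which takes part in assembling respiratory complexes, rose from 54.9 ± 3.66 to 70.9 ± 2.33 FPKM (log2 fold change 0.37, SE 0.056, adjusted p = 0.0412). The other 2 calls fall outside the naming rule and were chosen after their values were seen: 1700092M07Rik rose (422 ± 32.4 against 305 ± 18.5 FPKM), and the actin-capping gene Capg fell (0.553 ± 0.0874 against 1.71 ± 0.307 FPKM). Just outside the threshold, at an adjusted p of 0.0752, were Lsm3 (47.5 ± 0.615 against 38.3 ± 1.4 FPKM), Spcs1 (276 ± 8.1 against 240 ± 6.05 FPKM), Prss55 (173 ± 4.18 against 151 ± 1.4 FPKM) and Sgf29 (214 ± 8.43 against 175 ± 6.06 FPKM) above control. Below it were Arhgap5 (25 ± 0.273 against 30.2 ± 1.05 FPKM), Usp34 (19.7 ± 0.0781 against 23.2 ± 0.608 FPKM), Adi1 (3.13 ± 0.0985 against 5.36 ± 0.788 FPKM), Ranbp2 (12.4 ± 0.365 against 15 ± 0.773 FPKM) and Klk1b21 (6.8 ± 2.24 against 21.3 ± 5.28 FPKM). An unadjusted p under 0.05 was found for 2071 genes, and values did not overlap for 23.2% of genes, where chance gives 10%. The 3 calls became 0 without control 2, control 3, AOS 1, AOS 3, HFD-AOS 2, HFD-AOSFMT 1 or HFD-AOSFMT 2, 1 without AOS 2 or HFD-conFMT 1, 6 without HFD 1, 15 without HFD 2, 9 without HFD-AOS 3 and 44 without HFD-AOS 1, and array weights gave 240. The epididymal gene Crisp1 was at 159 FPKM in control 3, and without that library and HFD-conFMT 2 the count was 0. Of the processing alternatives, calls ended for the round spermatid and elongating spermatid lists with quantile normalization and for the fatty acid synthesis list without both control 3 and HFD-conFMT 2. Leaving out 1 library ended the call of the Leydig cell list without control 1 or AOS 3 (adjusted p = 0.0745 to 0.283) and of the fatty acid synthesis list in 6 of 18 fits (adjusted p = 0.0507 to 0.229).

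**Figure D1:**
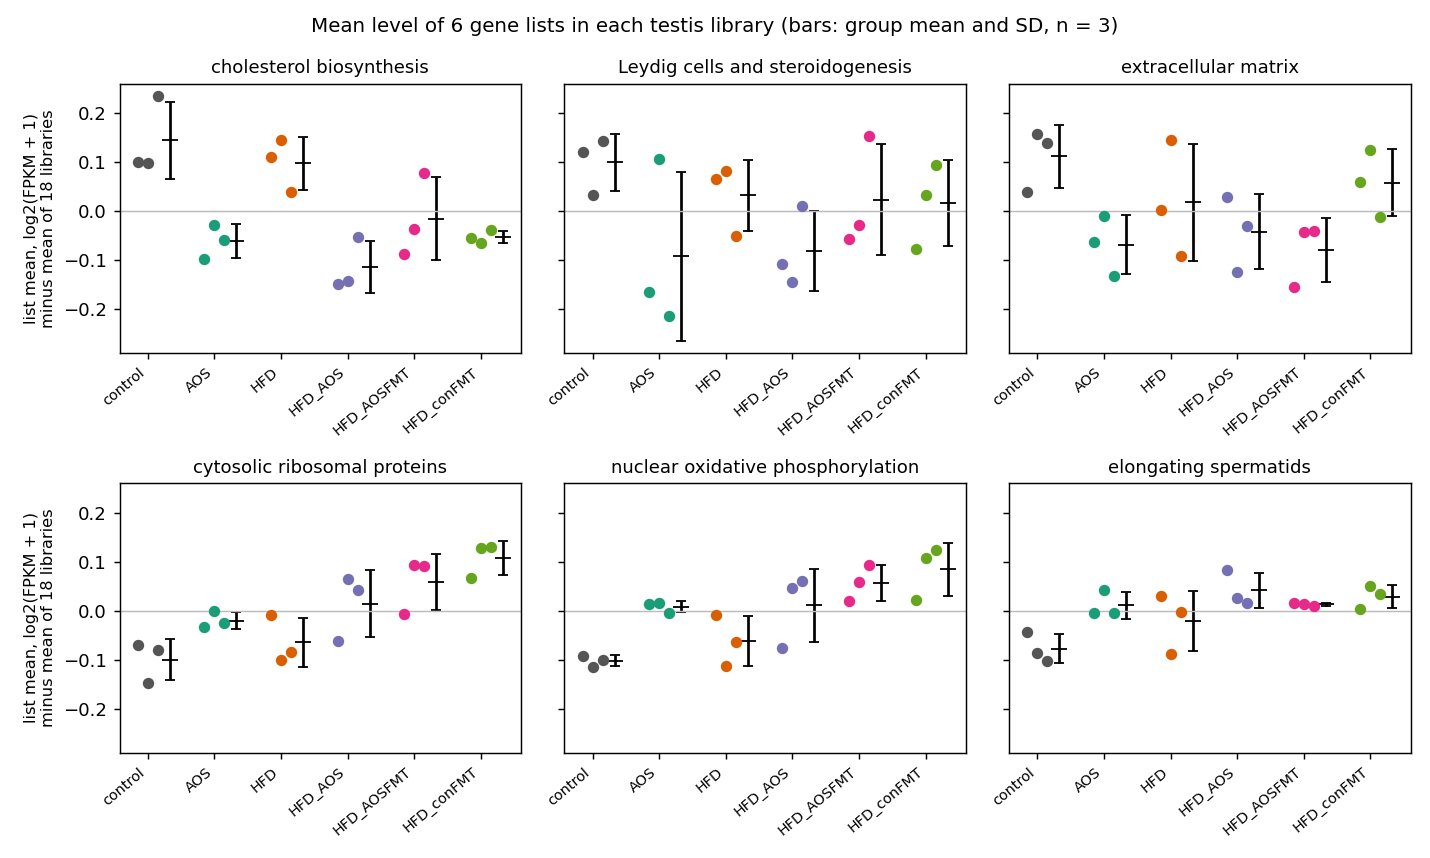
Mean level of 6 gene lists in each of the 18 libraries, as the list mean of log2(FPKM + 1) minus its mean over all libraries. Points are libraries and bars are group means with SD (n = 3); the cholesterol biosynthesis list lay above 0 in all control and HFD libraries and below 0 in all AOS, HFD-AOS and HFD-conFMT libraries.

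The comparison of HFD-AOS with HFD asked what AOS did in mice on the diet. Sterol synthesis transcripts were again lower. The cholesterol biosynthesis list fell with 20 of 23 members lower and a median log2 fold change of -0.24 (camera adjusted p = 2.3e-08). This call was lost with an adjusted p = 0.25 with an estimated correlation, and alternatives spanned 4.44e-10 to 0.25. Of its members 14 fell adjusted over the list alone, against 0 over all genes. All 11 members that fell in AOS against control were among these 14, where independent draws from the list would share 6.7. These comparisons have no library in common, but the same model gave both, with a shared residual spread for each gene. Members of low spread pass more easily in both, so the value from independent draws is no fair measure of the overlap. Msmo1 was at 14 ± 1.82 against 20 ± 2.67 FPKM, Tm7sf2, a sterol reductase, at 3.12 ± 0.477 against 4.49 ± 0.521 FPKM and Stard4, a cholesterol carrier, at 1.91 ± 0.12 against 2.54 ± 0.176 FPKM. The fatty acid synthesis list fell with 18 of 20 members lower (camera adjusted p = 0.00207), 6 of them adjusted over the list alone. That list had an adjusted p = 0.581 with an estimated correlation, within a range of 0.00017 to 0.581 over all alternatives. Me1 was at 145 ± 3.69 against 161 ± 2.02 FPKM, Elovl2 at 73.1 ± 1.44 against 80.9 ± 4.25 FPKM and Fads1 at 22.4 ± 2.26 against 29.4 ± 3.29 FPKM.

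The interferon response and the macrophage and leukocyte lists rose with AOS on the diet, while the inflammation list was not called (camera adjusted p = 0.619). In the interferon response list 8 of 10 members were higher (camera adjusted p = 0.043), 1 of them adjusted over the list alone. It had an adjusted p = 0.708 with an estimated correlation and 0.00621 to 0.708 over all alternatives. Relative to all libraries, the mean of that list was 0.327, 0.379 and 0.0392 in the HFD-AOS libraries, and it was highest in AOS 3, outside this comparison, at 0.57 against -0.182 and -0.198 in AOS 1 and AOS 2. Ifi27l2a was at 8.73 ± 2.73 against 2.71 ± 0.678 FPKM, Bst2 at 7.49 ± 1.4 against 4.48 ± 1.34 FPKM and the transcription factor Irf7 at 2.53 ± 1.04 against 0.98 ± 0.105 FPKM. The macrophage and leukocyte list rose (12 of 18 members higher, camera adjusted p = 0.0257), 0 of them adjusted over the list alone, with the complement gene C1qb at 16.1 ± 2.65 against 12.4 ± 0.983 FPKM and Tyrobp at 4.32 ± 1.54 against 3.06 ± 0.418 FPKM. With an estimated correlation the list had an adjusted p = 0.645, and all alternatives spanned 0.0135 to 0.645. The round spermatid list rose (20 of 30 members higher, camera adjusted p = 0.0266), with Tssk3 at 206 ± 12.4 against 187 ± 2.03 FPKM. An estimated correlation gave the round spermatid list an adjusted p = 0.645, in a range of 0.000295 to 0.645 over all alternatives. The elongating spermatid list rose too (16 of 28 members higher, camera adjusted p = 0.0342), whose median of 0.027 turned to -0.039 with quantile normalization. Over all alternatives the elongating spermatid list spanned 0.00321 to 0.645, with an adjusted p = 0.645 with an estimated correlation. In that list 1 member rose adjusted over the list alone, and Prm3 was at 879 ± 103 against 615 ± 104 FPKM. The ribosomal protein list (56 of 82 members higher, camera adjusted p = 8.6e-07) and the oxidative phosphorylation list (52 of 82 members higher, camera adjusted p = 0.00276) rose as well, with Rpl27 at 156 ± 11.8 against 130 ± 6.93 FPKM and Ndufa5 at 125 ± 9.8 against 105 ± 6.49 FPKM. The ribosomal protein list had an adjusted p = 0.645 with an estimated correlation, and 1.69e-13 to 0.645 over all alternatives. The oxidative phosphorylation list had an adjusted p = 0.708 with an estimated correlation, and 1.81e-09 to 0.708 over all alternatives. HFD-AOS 1 stood apart from the other libraries on principal component 3, at 19.3 with no other above 7.22. Relative to all libraries, its means of these lists were -0.0622 and -0.0749, within the range of the HFD libraries, against 0.0655 and 0.0472 in HFD-AOS 2 and 0.0422 and 0.062 in HFD-AOS 3. Log2 fold changes correlated with transcript length at a Spearman rho of -0.177 and with GC share at 0.294, and with the length and GC adjustment the ribosomal protein list stayed called and the oxidative phosphorylation list did not.

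By limma 0 genes were called between HFD-AOS and HFD (lowest adjusted p = 0.159, for Tmem89), with 1664 genes at an unadjusted p under 0.05 and no overlap of values for 13.4% of genes against 10% by chance. The smallest p-values above HFD were those of Tmem89 (80.1 ± 8.08 against 62.8 ± 1.73 FPKM), Tmem190 (157 ± 10.1 against 130 ± 5.54 FPKM), Saxo2 (11.7 ± 0.777 against 9.14 ± 0.489 FPKM), the actin-binding peptide Tmsb10 (2745 ± 407 against 1943 ± 170 FPKM) and Taf10 (132 ± 8.76 against 111 ± 7.01 FPKM). Below HFD they were Abcc12 (36.2 ± 1.48 against 41.8 ± 0.306 FPKM), the meiotic helicase Hfm1 (4.82 ± 0.266 against 6.2 ± 0.105 FPKM), Stt3b (151 ± 1.08 against 181 ± 16.7 FPKM), Sprtn (78.2 ± 1.98 against 91.1 ± 1.96 FPKM) and Naa15 (20.5 ± 0.502 against 23.6 ± 0.576 FPKM). Without HFD-AOS 1 the count was 1 and without HFD-AOS 3 it was 4. Of the processing alternatives, calls ended for the round spermatid, elongating spermatid, interferon response and oxidative phosphorylation lists with quantile normalization, for the round spermatid, elongating spermatid, macrophage and leukocyte, interferon response and oxidative phosphorylation lists with the length and GC adjustment, for the elongating spermatid, macrophage and leukocyte and interferon response lists with no filter on low values, for the elongating spermatid and interferon response lists with array weights, for the macrophage and leukocyte list with a mean of at least 5 FPKM required and for the interferon response list with trimmed-mean scaling and with a pseudocount of 0.1. Leaving out 1 library ended the call of the round spermatid list in 4 of 18 fits (adjusted p = 0.0514 to 0.289), of the elongating spermatid list without HFD 2, HFD-AOS 1 or HFD-AOS 2 (adjusted p = 0.0753 to 0.373), of the macrophage and leukocyte list without HFD 1, HFD-AOS 1 or HFD-AOS 3 (adjusted p = 0.0563 to 0.18), of the fatty acid synthesis list without HFD-AOS 2 (adjusted p = 0.0753), of the interferon response list in 4 of 18 fits (adjusted p = 0.0713 to 0.281) and of the oxidative phosphorylation list without HFD 2, HFD-AOS 2 or HFD-AOS 3 (adjusted p = 0.0753 to 0.18).

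Whether AOS acted differently with and without the diet was tested as the difference of both effects. By limma 0 genes differed (lowest adjusted p = 0.521, for Adi1), with 899 at an unadjusted p under 0.05, and 0 of the 29 lists differed (lowest adjusted p = 0.218, for the oxidative phosphorylation and extracellular matrix lists). For the cholesterol biosynthesis list the camera test leaned down (adjusted p = 0.922) while the median difference was above 0, at 0.0075.

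**Figure D2:**
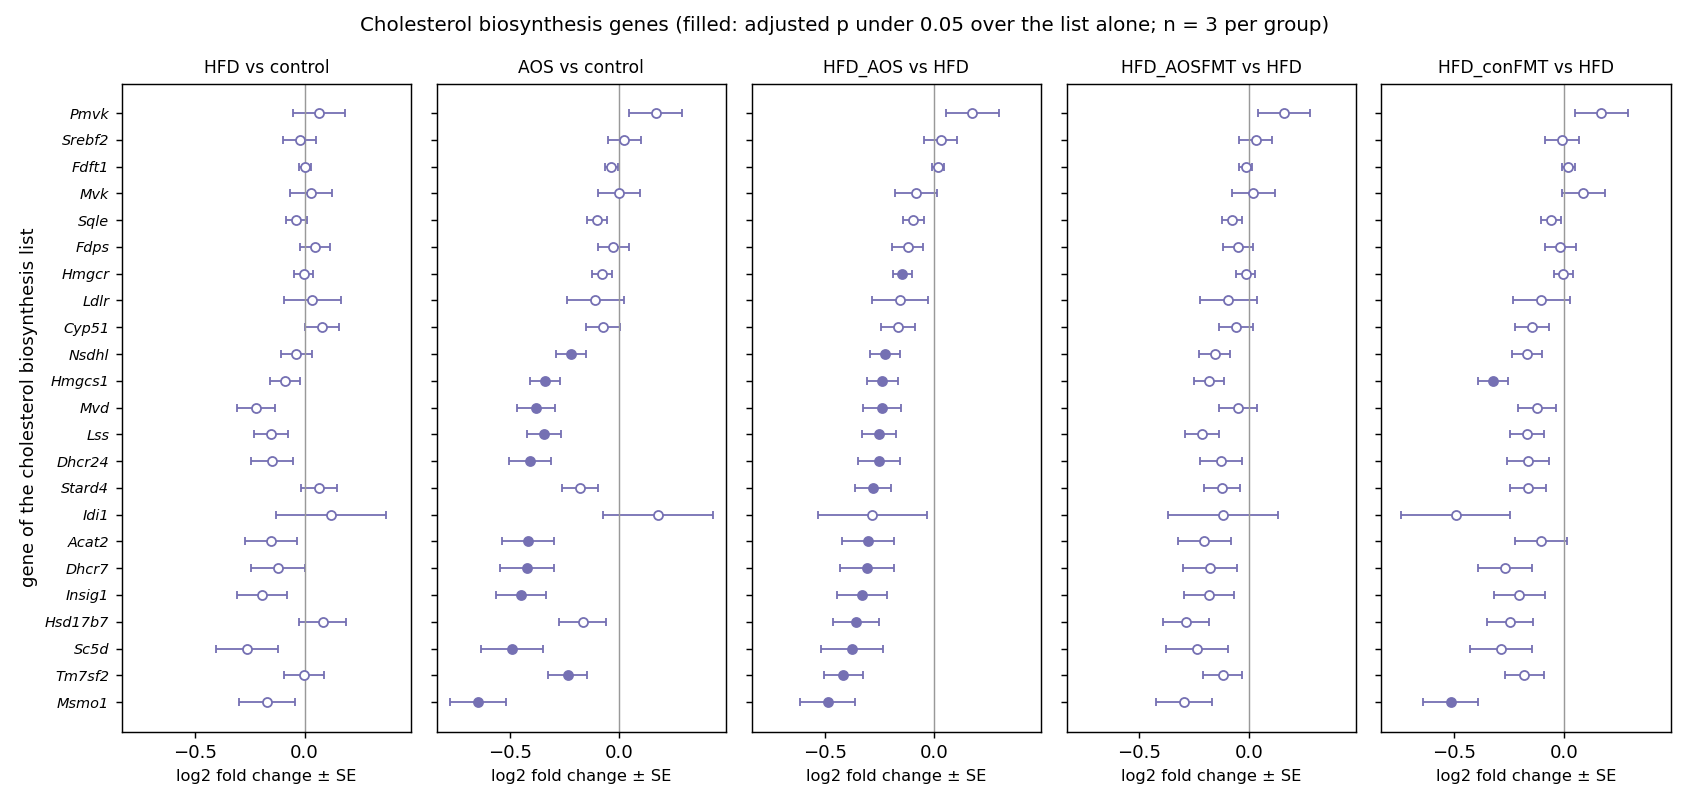
Log2 fold change on the log2(FPKM + 1) scale, with SE, of 23 cholesterol biosynthesis genes in 5 comparisons (n = 3 per group), each gene a line and filled points marking an adjusted p under 0.05 over the list alone. Filled points numbered 11 for AOS against control, 14 for HFD-AOS against HFD, 2 for HFD-conFMT against HFD and 0 in the other panels.

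The comparison of HFD-AOSFMT with HFD asked what the FMT labelled AOS did on the diet. Kap, the androgen-regulated protein of the kidney proximal tubule (chromosome 6, 133849851 to 133853762, mm10), was at 37.7, 31.5 and 36.3 FPKM in the 3 HFD-AOSFMT libraries, at 0.15 in HFD 3 and listed at 0 in all other libraries (adjusted p = 1.82e-16, limma). Other kidney genes, singled out after their values were seen, were also highest there at low levels. Slc34a1, a phosphate transporter, was at 0.967 ± 0.246 FPKM with no other library above 0.19, and Acsm2 at 0.437 ± 0.0666 with no other library above 0.01. Dgcr6 (chromosome 16, 18052860 to 18071632) rose from 62.6 ± 3.37 to 76.5 ± 1.46 FPKM (log2 fold change 0.29, SE 0.044, adjusted p = 0.0394). Hagh, which detoxifies methylglyoxal adducts (chromosome 17, 24840143 to 24864450), rose from 141 ± 5.33 to 167 ± 2.6 FPKM (log2 fold change 0.24, SE 0.037, adjusted p = 0.0394).

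Lists of ribosomal proteins and of oxidative phosphorylation rose after this FMT. The log2 fold changes correlated with transcript length at a Spearman rho of -0.265 and with GC share at 0.241, and both lists, which hold short transcripts, stayed called with the length and GC adjustment. Of the ribosomal protein list 76 of 82 members were higher (camera adjusted p = 2.73e-13), 3 of them adjusted over the list alone, with Rpl11 at 373 ± 20.1 against 305 ± 23.8 FPKM. All alternatives put the ribosomal protein list at 2.37e-17 to 0.308, with an adjusted p = 0.308 with an estimated correlation. Of the oxidative phosphorylation list 74 of 82 were higher (camera adjusted p = 1.83e-12), 2 of them adjusted over the list alone, with Sdhd, of complex II, at 23.7 ± 0.435 against 20 ± 0.506 FPKM and Ndufb9 at 113 ± 3.42 against 100 ± 2.85 FPKM. This call was lost with an adjusted p = 0.308 with an estimated correlation, and alternatives spanned 1.02e-14 to 0.308. The cholesterol biosynthesis list fell, with 20 of 23 members lower and a median of -0.12 (camera adjusted p = 0.00088). That list had an adjusted p = 0.638 with an estimated correlation, within a range of 2.99e-06 to 0.638 over all alternatives. Lss was at 2.92 ± 0.286 against 3.54 ± 0.207 FPKM, Hsd17b7 at 1.17 ± 0.188 against 1.64 ± 0.126 FPKM and Hmgcs1 at 27.5 ± 1.52 against 31.4 ± 2.29 FPKM. Fatty acid synthesis (17 of 20 members lower, camera adjusted p = 0.025), extracellular matrix (23 of 26 members lower, camera adjusted p = 0.00641) and smooth muscle (8 of 10 members lower, camera adjusted p = 0.0428) lists fell. The fatty acid synthesis list had an adjusted p = 0.638 with an estimated correlation, and 0.00411 to 0.638 over all alternatives. The extracellular matrix list had an adjusted p = 0.654 with an estimated correlation, and 0.000354 to 0.654 over all alternatives. The smooth muscle list had an adjusted p = 0.654 with an estimated correlation, and 0.000609 to 0.654 over all alternatives. Members of these lists included the desaturase Fads2 at 72 ± 8.07 against 86.2 ± 6.55 FPKM, lumican (Lum) at 1.67 ± 0.0557 against 2.15 ± 0.228 FPKM and the smooth muscle actin Acta2 at 18.9 ± 3.66 against 22.8 ± 2.33 FPKM. In these 4 lists 0 members passed adjusted over the list alone.

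The comparison with this FMT had 1287 genes at an unadjusted p under 0.05, and values did not overlap for 17.2% of genes, where chance gives 10%. After the called genes, the smallest p-values above HFD were those of Pcbd2 (3.69 ± 0.433 against 1.75 ± 0.344 FPKM) and Taf10 (137 ± 5.71 against 111 ± 7.01 FPKM). Below HFD they were Fam71a (84.7 ± 3.72 against 97.8 ± 2.57 FPKM), Serinc2 (4.84 ± 0.194 against 6.5 ± 0.742 FPKM), Samd11 (3.11 ± 0.366 against 4.34 ± 0.461 FPKM), Kpna3 (9.38 ± 0.367 against 11.3 ± 0.686 FPKM) and Cep128 (101 ± 2.42 against 111 ± 1.29 FPKM). Kap was called in all 18 fits that left out 1 library, but the count of 3 became 1 without control 2, control 3, AOS 1, AOS 2, AOS 3, HFD 2, HFD 3, HFD-AOSFMT 1, HFD-AOSFMT 2, HFD-AOSFMT 3, HFD-conFMT 2 or HFD-conFMT 3 and 6 without HFD-AOS 1, and it was 26 with no filter on low values. Of the processing alternatives, calls ended for the smooth muscle and extracellular matrix lists with a mean of at least 5 FPKM required and for the smooth muscle list with quantile normalization and with array weights. Fits without 1 library lost the call of the smooth muscle list in 8 of 18 fits (adjusted p = 0.05 to 0.265), of the cholesterol biosynthesis list without HFD-AOSFMT 1 (adjusted p = 0.0516), of the fatty acid synthesis list in 4 of 18 fits (adjusted p = 0.0622 to 0.0957) and of the extracellular matrix list without HFD 2 or HFD-AOSFMT 1 (adjusted p = 0.211 to 0.263).

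**Figure D3:**
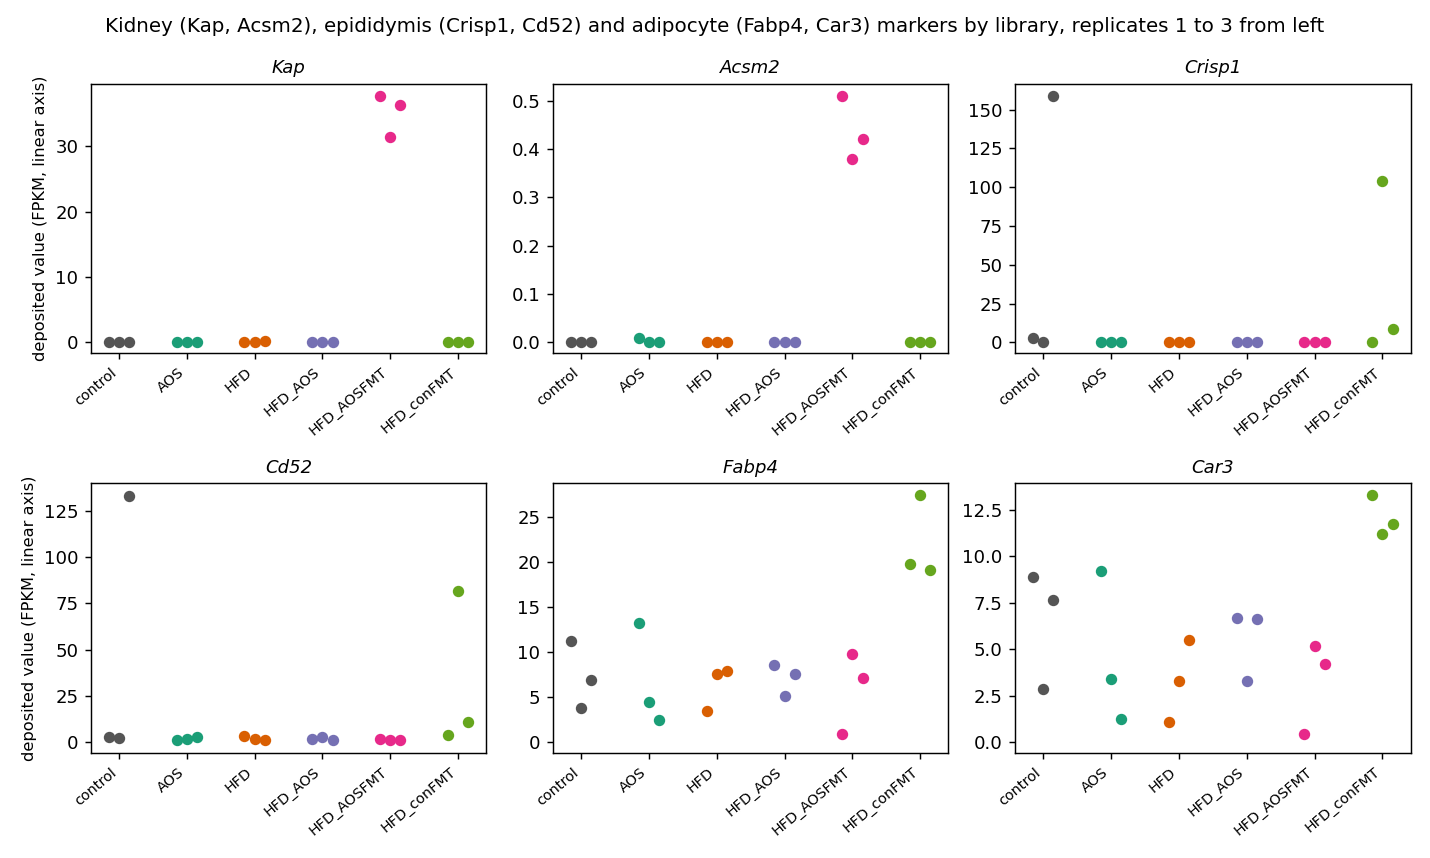
FPKM in each library, on linear axes from 0, of kidney (Kap, Acsm2), epididymis (Crisp1, Cd52) and adipocyte (Fabp4, Car3) genes; each point is a library, with replicates 1 to 3 from left to right in each of the 6 groups. Kap and Acsm2 were high in the 3 HFD-AOSFMT libraries, Crisp1 and Cd52 in control 3 and HFD-conFMT 2, and Fabp4 and Car3 in the 3 HFD-conFMT libraries.

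The comparison of HFD-conFMT with HFD gave the effect of the FMT labelled control. After this FMT too the ribosomal protein list rose, with 76 of 82 members higher and a median log2 fold change of 0.17 (camera adjusted p = 1.49e-19). With an estimated correlation the list had an adjusted p = 0.178, and all alternatives spanned 7.63e-23 to 0.178. Of its members 23 rose adjusted over the list alone, against 0 over all genes. Rpl13 was at 487 ± 16.8 against 403 ± 20.1 FPKM, Rps13 at 321 ± 5.98 against 272 ± 12.8 FPKM and Rpl32 at 700 ± 23.7 against 603 ± 30.1 FPKM. The oxidative phosphorylation list rose with 78 of 82 members higher (camera adjusted p = 3.44e-13), with Sdhd at 23.7 ± 0.898 against 20 ± 0.506 FPKM and Ndufa4 at 58.1 ± 3.04 against 47.5 ± 3.37 FPKM. An estimated correlation gave the oxidative phosphorylation list an adjusted p = 0.263, in a range of 8.31e-16 to 0.263 over all alternatives. Beside these lists of short transcripts, log2 fold changes correlated with transcript length at a Spearman rho of -0.281 and with GC share at 0.282, and both stayed called with the length and GC adjustment. The macrophage and leukocyte list rose with 17 of 18 members higher (camera adjusted p = 2.27e-05), 3 of them adjusted over the list alone. Over all alternatives the macrophage and leukocyte list spanned 1.88e-06 to 0.263, with an adjusted p = 0.263 with an estimated correlation. Lysozyme Lyz2 was at 22.4 ± 2.79 against 14.8 ± 0.682 FPKM, Tyrobp at 5.4 ± 0.426 against 3.06 ± 0.418 FPKM and C1qc at 7.78 ± 0.525 against 5.75 ± 0.245 FPKM. The blood list rose as well (5 of 5 members higher, camera adjusted p = 0.0491), with Hba-a1 at 86.3 ± 6.08 against 62.1 ± 22.9 FPKM, and in the same libraries the fat cell genes Fabp4 and Car3, singled out after their values were seen, were at 22.1 ± 4.59 against 6.3 ± 2.48 FPKM and 12.1 ± 1.07 against 3.28 ± 2.2 FPKM. The blood list had an adjusted p = 0.274 with an estimated correlation, and 0.0228 to 0.593 over all alternatives. The adipocyte list itself was not called here, with 6 of 8 members higher and a camera adjusted p = 0.0634.

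Sterol synthesis transcripts were lower after the control FMT too, in a comparison that shares the HFD libraries with those of HFD-AOS and HFD-AOSFMT. The cholesterol biosynthesis list fell with 20 of 23 members lower and a median of -0.16 (camera adjusted p = 4.15e-05), and 2 members, Hmgcs1 (24.9 ± 1.73 against 31.4 ± 2.29 FPKM) and Msmo1 (13.7 ± 2 against 20 ± 2.67 FPKM), fell adjusted over the list alone. All alternatives put the cholesterol biosynthesis list at 2.68e-06 to 0.274, with an adjusted p = 0.274 with an estimated correlation. The fatty acid synthesis list fell (15 of 20 members lower, camera adjusted p = 0.0279), with 1 member down adjusted over the list alone and Fads2 at 64.7 ± 9.61 against 86.2 ± 6.55 FPKM. This call was lost with an adjusted p = 0.538 with an estimated correlation, and alternatives spanned 0.00857 to 0.538. The meiotic spermatocyte list fell (29 of 39 members lower, camera adjusted p = 0.0279), with 3 members down and 1 up adjusted over the list alone. That list had an adjusted p = 0.606 with an estimated correlation, within a range of 0.00745 to 0.606 over all alternatives. Piwil1, which binds piRNAs, was at 102 ± 2 against 117 ± 3.54 FPKM, the synaptonemal complex gene Sycp2 at 71.4 ± 2.57 against 82.3 ± 3.81 FPKM and Ovol1 at 5.09 ± 0.247 against 3.86 ± 0.4 FPKM. By limma 0 genes were called (lowest adjusted p = 0.0651, for LOC108168657), with 1607 at an unadjusted p under 0.05 and no overlap for 20.2% of genes against 10% by chance. The smallest p-values above HFD were those of Capg (2.2 ± 0.236 against 0.863 ± 0.325 FPKM), Rps19bp1 (12.3 ± 1.26 against 8.75 ± 0.644 FPKM), Dgcr6 (75.1 ± 3.18 against 62.6 ± 3.37 FPKM), Rpl13 and the chaperone Dnajb1 (117 ± 1.83 against 104 ± 0.863 FPKM). Below HFD, besides Piwil1 and Hmgcs1, were Polr2a (24.3 ± 0.331 against 28.6 ± 1.32 FPKM), Klk1b21 (2.53 ± 0.964 against 8.27 ± 3.54 FPKM) and Zhx1 (11.1 ± 0.171 against 13 ± 0.31 FPKM). The count of 0 became 17 without HFD-AOS 1, 1 without AOS 3 or HFD 2, 9 with array weights and 3 with no filter on low values. Crisp1 was at 104 FPKM in HFD-conFMT 2, and without that library and control 3 the count was 1. Of the processing alternatives, calls ended for the meiotic spermatocyte and blood lists with the length and GC adjustment and for the blood list with no filter on low values, with trimmed-mean scaling, with a pseudocount of 0.1 and with array weights. Leaving out 1 library ended the call of the meiotic spermatocyte list without HFD 2 or HFD-conFMT 3 (adjusted p = 0.0547 to 0.0852), of the blood list in 12 of 18 fits (adjusted p = 0.0581 to 0.593) and of the fatty acid synthesis list without HFD 1, HFD 2 or HFD-conFMT 2 (adjusted p = 0.063 to 0.0802).

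The comparison of HFD-AOSFMT with HFD-conFMT set the 2 FMT labels against each other. Kap was the only gene called by limma among 13105 (adjusted p = 1.48e-16), and it was listed at 0 in all 3 HFD-conFMT libraries. Extracellular matrix, smooth muscle and macrophage lists were lower under the AOS label of the FMT than under the control label. None of these calls held without HFD-AOSFMT 1. Falls and rises here compare the 2 labels, not either FMT with HFD. Relative to all libraries, mean levels of the macrophage and leukocyte list were -0.128 in HFD, -0.0312 in HFD-AOSFMT and 0.143 in HFD-conFMT. They were -0.209, -0.224 and 0.455 for the adipocyte list and -0.0642, 0.0598 and 0.108 for the ribosomal protein list. The extracellular matrix and smooth muscle lists were lowest in HFD-AOSFMT, at -0.0789 and -0.1. The extracellular matrix list fell with 22 of 26 members lower (camera adjusted p = 1.95e-05), 1 of them adjusted over the list alone, with fibronectin (Fn1) at 2.74 ± 0.246 against 3.56 ± 0.376 FPKM and Lum at 1.67 ± 0.0557 against 2.22 ± 0.176 FPKM. It had an adjusted p = 0.472 with an estimated correlation and 2.07e-06 to 0.544 over all alternatives. The smooth muscle list fell (8 of 10 members lower, camera adjusted p = 0.00171), with Acta2 at 18.9 ± 3.66 against 23.9 ± 4.02 FPKM. With an estimated correlation the list had an adjusted p = 0.472, and all alternatives spanned 2.07e-06 to 0.544. The macrophage and leukocyte list fell (16 of 18 members lower, camera adjusted p = 0.00171), with Lyz2 at 16.6 ± 1.48 against 22.4 ± 2.79 FPKM and the class II gene H2-Aa at 4.89 ± 1.15 against 8.54 ± 2.82 FPKM. An estimated correlation gave the macrophage and leukocyte list an adjusted p = 0.472, in a range of 0.000129 to 0.544 over all alternatives. The adipocyte list fell (6 of 8 members lower, camera adjusted p = 0.0198), 2 members adjusted over the list alone, with the fatty acid binding protein Fabp4 at 5.95 ± 4.54 against 22.1 ± 4.59 FPKM and Car3 at 3.29 ± 2.51 against 12.1 ± 1.07 FPKM. Over all alternatives the adipocyte list spanned 2.1e-05 to 0.544, with an adjusted p = 0.472 with an estimated correlation. The immediate early response list fell (13 of 16 members lower, camera adjusted p = 0.0145), with Ier2 at 1.9 ± 0.413 against 2.81 ± 0.659 FPKM. The immediate early response list had an adjusted p = 0.472 with an estimated correlation, and 0.00037 to 0.919 over all alternatives. The ribosomal protein list fell (67 of 82 members lower, camera adjusted p = 0.00263), with Rps13 at 300 ± 8.74 against 321 ± 5.98 FPKM, and the meiotic spermatocyte list rose (27 of 39 members higher, camera adjusted p = 0.0362), with Piwil1 at 107 ± 1.73 against 102 ± 2 FPKM. The ribosomal protein list had an adjusted p = 0.845 with an estimated correlation, and 8.5e-05 to 0.867 over all alternatives. The meiotic spermatocyte list had an adjusted p = 0.778 with an estimated correlation, and 0.0126 to 0.908 over all alternatives.

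Between the FMT labels 409 genes had an unadjusted p under 0.05, fewer than the 655 that chance gives. Values did not overlap for 10.1% of genes, where chance gives 10%. Neither count points to gene changes beyond Kap. After Kap, the smallest p-values were those of Txndc11 (4.66 ± 0.223 against 3.52 ± 0.394 FPKM), the lamin Lmna (8.29 ± 0.75 against 6.71 ± 0.476 FPKM), Eif4e2 (65 ± 1.63 against 56.2 ± 1.75 FPKM) and Polr2k (20.9 ± 2.21 against 14.5 ± 1.04 FPKM) on the higher side. On the lower side they were the Polycomb gene Eed (11.5 ± 0.434 against 14.3 ± 0.546 FPKM), Mrpl22 (29.8 ± 1.09 against 34 ± 1.2 FPKM), Fn1, Ap4s1 (11.4 ± 0.242 against 13.1 ± 0.518 FPKM) and keratin Krt8 (3.19 ± 0.781 against 4.97 ± 0.2 FPKM). Crisp1 was at 104 FPKM in HFD-conFMT 2 and 8.6 in HFD-conFMT 3, and leaving out HFD-conFMT 2 with control 3 reduced the 7 list calls to 2. Leaving out HFD-AOSFMT 1 alone ended all 7. Relative to all libraries, its mean was -0.791 for the adipocyte list, against 0.0951 and 0.0231 in HFD-AOSFMT 2 and 3. For the extracellular matrix list it was -0.155, against -0.0416 and -0.0402. Of the processing alternatives, calls ended for the meiotic spermatocyte list with no filter on low values and with the length and GC adjustment, for the meiotic spermatocyte, smooth muscle, adipocyte, immediate early response and ribosomal protein lists without both control 3 and HFD-conFMT 2, for the adipocyte, immediate early response and extracellular matrix lists with a mean of at least 5 FPKM required and for the adipocyte list with array weights. Fits without 1 library lost the call of the meiotic spermatocyte list in 5 of 18 fits (adjusted p = 0.0527 to 0.246), of the smooth muscle list without HFD-AOSFMT 1 or HFD-conFMT 2 (adjusted p = 0.0708 to 0.0959), of the macrophage and leukocyte list without HFD-AOSFMT 1 or HFD-conFMT 3 (adjusted p = 0.0663 to 0.0713), of the adipocyte list without HFD-AOSFMT 1, HFD-conFMT 1 or HFD-conFMT 2 (adjusted p = 0.0613 to 0.186), of the immediate early response list without HFD-AOSFMT 1, HFD-AOSFMT 2 or HFD-conFMT 2 (adjusted p = 0.0781 to 0.805), of the extracellular matrix list without HFD-AOSFMT 1 (adjusted p = 0.0663) and of the ribosomal protein list without HFD-AOSFMT 1, HFD-conFMT 2 or HFD-conFMT 3 (adjusted p = 0.0545 to 0.809).

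Whether treated groups moved back toward control was asked of the genes the diet changed. As 0 genes were called between HFD and control, no gene could be counted as moved back in any treated group, and that count tests nothing. Across 13105 genes, which are not independent replicates, the log2 fold changes of HFD against control correlated with those of HFD-AOS against HFD at r = -0.238, where unchanged groups that share the HFD libraries gave -0.491 on average over 1000 draws. For HFD-AOSFMT the values were -0.258 and -0.492, and for HFD-conFMT -0.41 and -0.495. The covariances were -0.00518, -0.00545 and -0.00954, against -0.00876, -0.00876 and -0.00881 without any effect. All 3 correlations lay within the 95% range of the simulated ones. For pairs of comparisons without a shared library, r was 0.179 between AOS against control and HFD-AOS against HFD, 0.173 between AOS against control and HFD-AOSFMT against HFD-conFMT, and 0.195 between HFD against control and HFD-AOSFMT against HFD-conFMT, all within the simulated range. Beside AOS against control, r was 0.182 for HFD-AOSFMT against HFD and 0.00928 for HFD-conFMT against HFD, both within the simulated range.

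The limma F test over all 6 groups called 43 genes, and control had the lowest mean in 22 of them and the highest in 10. After Kap came the kallikrein Klk1b21 (adjusted p = 0.0118), at 21.3 ± 5.28 FPKM in control and 2.53 ± 0.964 in HFD-conFMT, and Capg (adjusted p = 0.0118), at 0.553 ± 0.0874 in AOS and 2.2 ± 0.236 in HFD-conFMT. Hmgcs1 (adjusted p = 0.0466) and Msmo1 (adjusted p = 0.0489) were among the 43, all of which were read after their values were seen. The count was 2 without control 1, control 2 or HFD-conFMT 2, 3 without AOS 1, HFD 3, HFD-AOSFMT 2, HFD-AOSFMT 3 or HFD-conFMT 3, 4 without control 3, 6 without HFD-AOSFMT 1, 11 without HFD 2 or HFD-AOS 2, 15 without HFD-conFMT 1, 16 without AOS 3, 79 without HFD-AOS 1 and 146 without HFD-AOS 3.

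Of a panel of 16 steroidogenic, germ cell and Sertoli cell genes, 15 were measured and 0 were called by limma in any comparison. The counts at an unadjusted p under 0.05 were 0 for HFD against control, 6 for AOS against control, 6 for HFD-AOS against HFD, 1 for HFD-AOSFMT against HFD, 3 for HFD-conFMT against HFD and 0 between the FMT labels. Star, which brings cholesterol into mitochondria, was at 30.3 ± 5.17 against 47.6 ± 5.39 FPKM in HFD-AOS against HFD, and Hsd3b1 at 120 ± 12.4 against 90.3 ± 10.4 FPKM in HFD-conFMT against HFD. The fixed lists called in no comparison had a lowest adjusted p of 0.272 for spermatogonia, 0.141 for Sertoli cells, 0.0529 for endothelium, 0.0916 for fatty acid oxidation and 0.12 for the blood-testis barrier. It was 0.252 for antioxidant defence, 0.293 for replication-dependent histones, 0.303 for cell cycle and DNA replication, 0.355 for glycolysis and lactate and 0.459 for inflammation. It was 0.619 for both endoplasmic reticulum stress and heat shock, 0.669 for retinoid metabolism and 0.793 for apoptosis. The epididymis list had 2 tested members and the list of mitochondrially encoded genes had 0, so neither was tested.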

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

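In this part the kidney marker test and the splits of the libraries were set before their results were seen, and no test was chosen after its result.

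Kap was singled out because the effect of FMT differed between the FMT labels in a test of the difference itself, with an adjusted p of 1.48e-16 (limma, HFD-AOSFMT against HFD-conFMT) and 35.2 ± 3.27 FPKM in HFD-AOSFMT (n = 3). To test for kidney RNA in these libraries, 40 other kidney markers were examined, of which the testis also expresses 7 at a mean of at least 1 FPKM, and 9 had all 3 HFD-AOSFMT libraries above the 15 others, where 0.049 is expected by chance, 1 did so for control and 0 for any other group. Of the most abundant kidney genes, Gpx3 was at 20.2 ± 1.65 FPKM (59.4 in control 3), Miox at 1.23 ± 0.232 (at most 0.86 elsewhere), Slc34a1 at 0.967 ± 0.246 (at most 0.19) and Umod at 0.27 ± 0.0964 (at most 0.08). These values are consistent with a small amount of kidney RNA in the HFD-AOSFMT libraries as a candidate source of Kap, and where it would have entered was not tested. An induction of Kap in the testis by the FMT labelled AOS also stays open, since the design gives that label to the same 3 libraries, but it would leave the 9 other markers without an account.

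Other splits of the 6 libraries of each comparison into 3 and 3 were fitted the same way, and 10 splits cannot give a share under 0.05. The real split gave 0 genes and the highest other 0 for HFD against control (10 of 10 gave as many). Where the real count is 0, every split gives as many by construction, and the count of splits tests nothing. The real count and the highest other were 3 and 1 for AOS against control (1 of 10), 0 and 0 for HFD-AOS against HFD (10 of 10), 3 and 0 for HFD-AOSFMT against HFD (1 of 10), 0 and 1 for HFD-conFMT against HFD (10 of 10) and 1 and 1 between the FMT labels (2 of 10). For lists the real count and the highest other were 6 and 5 for HFD against control (1 of 10), 8 and 8 for AOS against control (3 of 10), 8 and 7 for HFD-AOS against HFD (1 of 10), 6 and 7 for HFD-AOSFMT against HFD (3 of 10), 7 and 6 for HFD-conFMT against HFD (1 of 10) and 7 and 8 between the FMT labels (2 of 10). At an unadjusted p under 0.05 the real split and the highest other gave 884 and 1264 genes for HFD against control, 2071 and 1060 for AOS against control, 1664 and 1384 for HFD-AOS against HFD, 1287 and 725 for HFD-AOSFMT against HFD, 1607 and 738 for HFD-conFMT against HFD and 409 and 469 between the FMT labels. For the difference of the AOS effects the real count was also 0, so that 100 of 100 drawn splits gave as many by construction, which says nothing about chance. The highest other count, 74, points to a structure of the samples, and the groups themselves can be that structure, since these splits mix libraries of 4 groups. At an unadjusted p under 0.05 the real split gave 899 genes and the highest other 2681, and 34 of 100 splits gave as many as the real split. For the test over 6 groups, 1 of 100 drawn splits, the real one, gave 43 genes and the highest other gave 2. That count was thus rare among random groupings, as far as 100 splits can tell and if the libraries are independent. It fell to 2 without control 1, control 2 or HFD-conFMT 2.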

How the results depend on the processing

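The length and GC adjustment, leaving out control 3 with HFD-conFMT 2, and the list tests with other filters, trimmed-mean scaling or array weights were chosen after seeing the data, and the other alternatives before. Of 7731 values of 268 named genes under alternatives, 7599 kept their side of the threshold, 56 lost the call, 76 gained it and 0 called values changed sign, while 103 values that were not called did. Of 1215 values of 42 called lists, 977 kept both, 237 lost the call and in 1 the direction of the camera test reversed, for the elongating spermatid list in HFD-AOS against HFD with quantile normalization, whose median went from 0.027 to -0.039. In HFD against control the median of that list also changed sign with quantile normalization, to -0.0020, while the direction of the test did not. Among gene counts, the 0 of HFD against control became 1 with only its own groups in the model. The 3 of AOS against control became 0 with a fold threshold, with its own groups, with no filter, with quantile normalization and without control 3 and HFD-conFMT 2, 6 with trimmed-mean scaling, 7 with the length and GC adjustment and 240 with array weights. The 0 of HFD-AOS against HFD became 2 with no filter. The 3 of HFD-AOSFMT against HFD became 1 with a fold threshold, quantile normalization, trimmed-mean scaling, robust empirical Bayes and without those libraries, 5 with a mean of at least 5, 7 with array weights and 26 with no filter. With its own groups the count stayed at 3, but Gm7980 and Rpl37 took the place of Dgcr6 and Hagh. The length and GC adjustment gave 2, without Hagh. The 0 of HFD-conFMT against HFD became 1 with its own groups and without those libraries, 3 with no filter and 9 with array weights. The 1 between the FMT labels became 16 with no filter. The 43 of the test over 6 groups became 12 with quantile normalization, 4 with the length and GC adjustment, 1 without those libraries and 130 with array weights. Among list counts, estimated correlation gave 0 in all 6 comparisons, and fry gave 0, 1, 1, 0, 1 and 0 in the order reported. The 6 of HFD against control became 0 with quantile normalization, the 8 of HFD-AOS against HFD became 5 with no filter, 4 with quantile normalization and 3 with the length and GC adjustment, and the 7 between the FMT labels became 4 with a mean of at least 5 and 2 without those libraries. A fold threshold lowers a count by construction, and for the other changes, also those without 1 library, the cause was not tested. Leaving out 1 library gave 0 to 0, 0 to 44, 0 to 4, 1 to 6, 0 to 17 and 1 to 1 genes in the 6 comparisons, 0 to 0 for the difference of AOS effects and 2 to 146 over 6 groups, and 2 to 8, 7 to 11, 3 to 8, 2 to 7, 5 to 8 and 0 to 8 lists. With the replicate number as a block, HFD-AOSFMT against HFD gave 1 gene and the test over 6 groups 20, and the calls of the interferon list in HFD-AOS, smooth muscle in HFD-AOSFMT and blood in HFD-conFMT, each against HFD, ended. No sign was seen that the numbers pair the samples. Residuals of same-number libraries correlated at -0.102 to 0.0692, with 0 of 18 pairs over 0.1 and 6 of 18 libraries closest to their own number. The correlations covered only pairs within the 6 comparisons, so a pairing is not excluded. Relative depth differed by little (0.926 to 1.05), and because absolute depth is unknown, a value listed at 0 sets no limit on expression.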

Other observations

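The genes of the next 2 paragraphs and both tests of the cholesterol biosynthesis list were chosen after their results were seen, and the epididymis marker test was set before its result was seen.

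Several kallikrein genes, which Leydig cells express, were highest in control. Klk1b21 was at 21.3 ± 5.28 FPKM in control and between 2.53 ± 0.964 (HFD-conFMT) and 8.27 ± 3.54 (HFD) in the other groups (n = 3 each). Klk1b24 was at 22.3 ± 8.02 in control and at most 8.91 ± 3.7 elsewhere, and Klk1b27 at 16.6 ± 5.85 and at most 7 ± 2.79. These are near-identical copies whose reads cannot be fully told apart, and in the limma F test over the groups the adjusted p was 0.0118 for Klk1b21 and 0.033 for Klk1b24.

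Spink4, a trypsin inhibitor of the Kazal family, was at 15.3 ± 3.07 FPKM in HFD-AOS, 11.4 ± 3.56 in HFD-conFMT and 4 ± 0.556 in control (n = 3 each). The metallothionein Mt2 was at 569 ± 66.6 FPKM in HFD-AOS and 392 ± 38.2 in control. The transcript A530064D06Rik was lower in both FMT groups, at 0.427 ± 0.428 and 0.193 ± 0.0503 FPKM, than in the other groups, at 1.81 ± 1.18 to 2.48 ± 0.887. Among fat cell genes, Fabp4 was at 19.8, 27.4 and 19.1 FPKM in the HFD-conFMT libraries and at most 13.2 in any other, Car3 at 13.3, 11.2 and 11.8 against at most 9.2, and Lep at 0.43, 0.38 and 0.51 against at most 0.2. Plin4 was at 0.57, 0.57 and 0.77 against at most 0.56. Other fat cell genes did not follow them. Adipoq ranged from 9.43 to 14.9 over all 18 libraries, Cfd was highest in AOS 1 at 8.7 and Retn in HFD-AOS 1 at 4.4.

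Epididymal transcripts were high in 2 libraries of different groups, control 3 and HFD-conFMT 2. These also stood apart on principal component 1, which held 14.3% of the variance, at -22.58 and -11.71 with no other library below -3.86. Crisp1 was at 159 FPKM in control 3 and 104 in HFD-conFMT 2, with 8.6 in HFD-conFMT 3 and 2.71 in control 1, and Cd52 was at 133 and 81.4, Spink8 at 42.6 and 26.9 and Cuzd1 at 40.4 and 25.3 in these libraries. Of 45 other epididymis markers with a value, of which the testis also expresses 11 at a mean of at least 1 FPKM, 14 had these libraries as the highest 2 of 18, where 0.294 is expected by chance and no other pair had more than 2. Epididymis RNA in these libraries is a candidate source, and Lcn5 and Lcn8 were listed at 0 in both of them. No biological explanation was tested, as the libraries belong to different groups.

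The cholesterol biosynthesis list had mean log2 fold changes of -0.21 in AOS against control, -0.21 in HFD-AOS against HFD, -0.11 in HFD-AOSFMT against HFD and -0.15 in HFD-conFMT against HFD (SE 0.048 each). After an adjustment for transcript length and GC share, camera still called it in all 4, with adjusted p-values of 8.19e-08, 4.44e-10, 0.000132 and 3.66e-06, which argues against that trend as the whole cause. Whether a lower share of Leydig cells would lower the cholesterol and Leydig lists equally was not tested. The scale also understates the change of low genes. The cholesterol mean minus the Leydig mean was -0.0153, -0.0995 and -0.104 in the first 3 comparisons and -0.136 in HFD-conFMT against HFD (SE 0.0627). That difference therefore cannot decide whether a lower Leydig share was a cause. The Leydig list had mean log2 fold changes of -0.192 in AOS against control and -0.113 in HFD-AOS against HFD. In the FMT comparisons they were -0.00905 (HFD-AOSFMT) and -0.0156 (HFD-conFMT), with an SE of 0.0855 in all 4. No clear fall of the Leydig list was seen after FMT, and a lower Leydig share stays open. An effect of AOS or of FMT on sterol synthesis may also play a part and stays open: fry called the list in both AOS comparisons (adjusted p = 0.0165 and 0.0139), which share no library, and in neither FMT comparison (0.287 and 0.0855), and with an estimated correlation it was called in 0 of the 4.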
